A study of Homo sapiens with 14 samples.

How the data were processed

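HEK293 cells with inducible transgenes were induced with doxycycline at 0.5 to 1.0 ng/mL for 72 h, per the labels' protocols, and microsomes were treated with nuclease, solubilized and bound to Flag beads. Input and IP were digested with RNase to ribosome footprints, which were tailed, reverse transcribed by template switching and sequenced. The unit is the count: the authors deposited whole-number counts of footprints per gene symbol for each of 14 samples, not normalized. Cutadapt 4.1, Bowtie2 2.2.6, TopHat2 2.1.0 and the hg38 build are named, per the submitters' processing notes. The gene annotation, the strand setting and any use of the random bases of the primers to remove duplicates are not given in the sources used here, so duplicated fragments may remain in the counts and antisense or overlapping genes cannot be told apart.

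The files held 19440 symbols, of which 18968 matched the RefSeq table of GRCh38, used for positions, and 5 rows that name no gene, which were left out of library sizes and tests. Reads outside genes made up 9.02% to 12.1% of all counts in the EMC6 line and 2.53% to 4.71% in the other lines. The labels say that samples are separate replicates, but not that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates of a group correlated at r = 0.911 to 0.987 across genes, and no pair agreed within sampling noise (chi-square per degree of freedom 2.09 to 8.62). Depth limits low genes: the fold of a gene with 0 counts in a group is not given.

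All 14 libraries entered 1 fit in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with a mean per group of line and fraction, TMM normalization, filterByExpr (9458 genes kept) and a robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. This gave IP against input in each line and over the mean of the 3 lines, the differences of these changes between baits, and the EMC6 inputs against the mean of the other inputs. Since IP enriches part of the messages, TMM places the middle of the genes near 0: the median log2 change of all genes over the mean of the 3 lines was -0.19 with TMM, -0.09 with DESeq2 size factors, -0.61 with scaling on the secreted and luminal lists and -1.13 with library size alone. For the EMC6 inputs against the others it was 0.07, -0.01, 0.85 and 0.37. Lists are therefore given relative to that median.

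The design, the lists, the rule for named genes and most alternatives were set before the data were examined. The exact sign-flip test over pairs had been planned for predicted membrane segments, and its use on lists and classes of lists was chosen after the data were seen, as were the direct comparison of IP libraries, the fit without LSM4 and MAP4, the mean without the EMC6 line and the lists without the bait messages. Of 25 lists of gene symbols 24 had at least 3 tested members; the list encoded on mitochondrial DNA had none. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The rule named, for each IP/input comparison, the 10 genes with the largest rise and the 10 with the largest fall that passed the test, had at least 10 CPM in the higher fraction and moved the same way in every pair, then 5 a side for differences and inputs with at least 10 CPM in a group, the 10 EMC subunits, and up to 4 members per list. The text gives part of these, and some genes are not reported here. LSM4 and MAP4 also met the rule for inputs, and their shares were looked at after their values were seen.

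The labels give input and IP of a line the same replicate or batch number, and the IP was made from the input, so the numbers pair them within a line. Deviations from the group means of same-numbered samples correlated at 0.27 in the EMC6 line, 0.07 in the EMC7 line and 0.04 to 0.10 in the EMC10 line. With 2 replicates both deviations of a line mirror each other, so its 1 value is all the EMC6 and EMC7 lines give, and the pairing rests on the labels. In the EMC10 line each input correlated best with the IP of its own number. The blocked fit was run as an alternative, with DESeq2 1.42.0, other scalings and filters, a test against a fold of 1.5, fits without the baits and fits without each library.

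The steps were tested on simulated counts with the real depths and spread, where every library had the mean profile of the real inputs. Few genes were changed there, in random directions, whereas the data called 4790 of 9458 genes over the mean of the 3 lines. The simulation thus does not test the scaling, and its false calls do not measure those of the data. In the mean of the 3 lines 49.0%, 77.6%, 100% and 100% of genes planted at folds of 1.5, 2, 4 and 8 were recovered among 9029 genes, with 9 false calls of 167. In the EMC6 line the shares were 8.16%, 24.5%, 70.2% and 87.8%, with 10 false calls of 102. The planned comparison by predicted membrane segments was not run, as it needs protein sequences that were not used here.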

Results

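Ribosome-protected fragments were counted per gene in 14 libraries from HEK293 cells, a human embryonic kidney line, engineered to carry doxycycline-inducible transgenes. The cells expressed a Flag-tagged subunit of the ER membrane protein complex (EMC), an insertase of the endoplasmic reticulum (ER). EMC6 was the bait in 1 line, made in an EMC6 knockout, and EMC7 and EMC10 were the baits in the other lines, whose labels name no knockout. Each line gave solubilized microsomes (input) and the material held by Flag beads (IP), with n = 2 of each for EMC6, n = 2 of each for EMC7 and n = 3 of each for EMC10. The counts on genes came to 1692490 to 1835892 per input and 515302 to 960279 per IP in the EMC6 line, 2397165 to 3395114 and 1477225 to 2248591 in the EMC7 line, and 2907065 to 3371471 and 1335235 to 1784496 in the EMC10 line. The EMC6 line was therefore the shallowest. Values are TMM-normalised CPM (counts scaled to library size) as mean ± SD, and log2 fold changes ± SE from the fit to 9458 genes, with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test.

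The baits and the other EMC subunits were examined first, since the baits check the labels. Footprints on EMC6 (chromosome 17, 3668812 to 3669665, GRCh38) rose from 23.8 ± 7.5 CPM in input to 4431 ± 151 CPM in IP with the EMC6 bait, a log2 change of 7.54 ± 0.25 (adjusted p = 7.19e-23). EMC7 (chromosome 15, 34084017 to 34101862) rose by 5.71 ± 0.28 with its own bait (adjusted p = 1.56e-12), and EMC10 (chromosome 19, 50476507 to 50490871) by 7.31 ± 0.18 with its own (adjusted p = 1.73e-26). Before normalization, the bait message took 14.4% to 15.0% of the counts in EMC7 IPs, 24.6% to 26.1% in EMC10 IPs and 0.431% to 0.449% in EMC6 IPs. The EMC6 message, whose gene was knocked out in the EMC6 line, had 51 and 85 counts in its inputs, 114 and 88 in EMC7 inputs and 133, 120 and 123 in EMC10 inputs; tagged and endogenous messages share these counts, so they do not check the knockout. In the inputs, EMC7 was 24.8-fold higher in its own line than in the other lines (adjusted p = 6.41e-12) and EMC10 was 17.1-fold higher (adjusted p = 5.73e-22), whereas EMC6 stood at 0.833-fold (adjusted p = 0.325). The series describes the tagged subunits as near endogenous in level, and footprints on a message do not measure the level of its protein.

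The multi-pass subunits moved apart. EMC3 and EMC4 messages rose with every bait, by 3.54 ± 0.10 and 3.51 ± 0.10 over the mean of the 3 lines, whereas MMGT1 rose by 0.72 ± 0.13 over that mean (-0.24 with library size alone) and EMC6 by 1.17 ± 0.24 and 1.09 ± 0.20 with the EMC7 and EMC10 baits. The EMC7 message also rose with the EMC6 bait (3.26 ± 0.26) and the EMC10 bait (2.90 ± 0.20). EMC1, a large type I subunit (chromosome 1, 19215660 to 19251524), rose by 2.23 ± 0.17 with EMC7, from 1032 ± 60 to 4845 ± 16 CPM, and by 0.76 ± 0.16 and 0.62 ± 0.13 with EMC6 and EMC10. The EMC10 message stood at 0.48 ± 0.21 with the EMC6 bait (adjusted p = 0.0951) and at 0.52 with IP and input paired in a replicate block (adjusted p = 0.00103). The cytosolic subunits EMC2, EMC8 and EMC9 did not pass the test with any bait, with mean log2 changes of -0.46 ± 0.22, -0.10 ± 0.22 and 0.05 ± 0.36. Under library size alone all 3 were called lower over the mean (-1.41, -1.05 and -0.89), EMC2 also with each bait and EMC8 with EMC7 and EMC10, and scaling on the secreted and luminal lists called EMC2 (-0.90) and EMC8 (-0.54) lower over the mean. Scaling by library size alone left EMC1 with EMC6 at 0.05 (adjusted p = 0.772) and turned EMC1 with EMC10 to -0.50 (adjusted p = 0.000127, a fall), EMC10 with EMC7 to -0.40, EMC6 with EMC10 to -0.03, and MMGT1 with EMC7 and EMC10 to -0.43 and -0.63 (adjusted p = 0.0783 and 0.00232). That scaling counts the bait message, 24.6% to 26.1% of EMC10 IPs and 14.4% to 15.0% of EMC7 IPs, which lowers every other gene there. Its part in each turn was not computed.

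**Figure D1:**
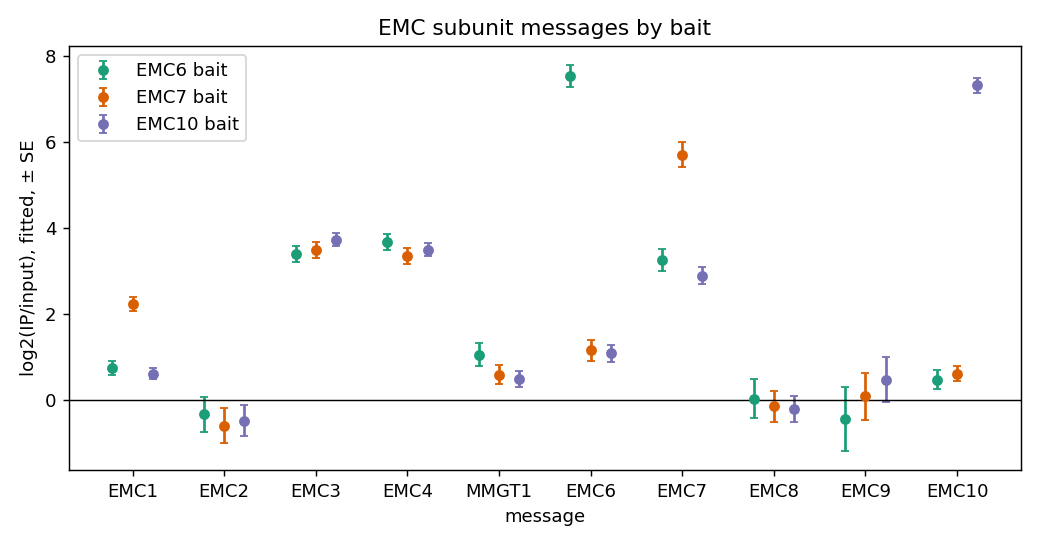
Fitted log2(IP/input) of the 10 EMC subunit messages (vertical axis, points with SE bars) for each bait (colours). EMC3 and EMC4 lie between 3.36 and 3.73 with every bait, whereas EMC1 reaches 2.23 with EMC7 and 0.76 or less with the other baits.

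With the EMC6 bait, the comparison of IP with input asks which messages had footprints enriched in the material held by Flag beads. No library of any line was an IP from cells without a tagged bait. What was held through the complex thus cannot be told apart from other material on the beads. After EMC6 itself, transporters and channels were among the largest rises. The calcium channel subunits CACNA1B and CACNA1C rose by 5.85 ± 0.38 and 5.28 ± 0.36 and the Na-K-Cl cotransporter SLC12A2 by 5.27 ± 0.19. CACNA1B had 3 and 8 counts in the inputs, against 40 and 132 in the IPs. The sodium-proton exchanger SLC9A3 and the transporter FLVCR2 had 1 count each over both inputs, against 5 and 28 counts and 7 and 13 counts in the IPs. ASB13, which encodes an ankyrin repeat protein, rose from 2.29 ± 0.34 to 79.7 ± 8.9 CPM. Of the fixed lists, 168 of 177 solute carriers rose and 1 fell, 88 of 92 multi-pass lipid enzymes rose (a list that also holds enzymes of GPI anchor and N-glycan synthesis), and 26 of 27 P-type pumps rose. The falls were led by TSTD2 (-2.86 ± 0.72), the endocytic scaffold ITSN2 (-2.64 ± 0.53) and MPHOSPH6 (-2.38 ± 0.64), none of which passed without IP replicate 2 of the EMC6 line (adjusted p = 0.140, 0.0632 and 0.274). In all, 1666 genes rose and 877 fell, against 1803 and 479 with DESeq2 size factors, 1133 and 2115 with scaling on the secreted and luminal lists, and 990 and 4320 with library size alone. Without IP replicate 2 of the EMC6 line 1000 rose and 165 fell, without input replicate 1 of that line 1308 and 443, and with the libraries of this line alone 1114 and 128.

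With the EMC7 bait, the ER ubiquitin ligase RNF26 rose by 4.16 ± 0.19 after EMC7 itself, SLC9A3 by 4.13 ± 0.64, the GPI mannosyltransferase PIGV by 4.09 ± 0.28 and the lysosomal cation channel TPCN2 by 3.89 ± 0.20. The actin-binding protein gene TAGLN went from 0.554 ± 0.126 CPM, 2 counts in each input, to 11.9 ± 3.5 CPM. All 18 ABC transporters and all 20 DHHC palmitoyltransferases rose, as did 88 of 90 ion channel subunits and 79 of 94 type II Golgi enzymes. Under library size alone 18, 12 and 78 of the first 3 lists rose, and 41 type II enzymes rose and 6 fell. SUDS3, a corepressor subunit, fell by 2.40 on the log2 scale (SE 0.55). In all, 1930 genes rose and 916 fell, against 1421 and 2674 with scaling on the secreted and luminal lists and 1001 and 6038 with library size alone. The genes that fell numbered 555, 432, 593 and 524 without input 1, IP 1, input 2 and IP 2 of the EMC7 line, and 540 with DESeq2.

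With the EMC10 bait, CACNA1C rose by 4.98 ± 0.27, RNF26 by 4.67 ± 0.16, PIGV by 4.31 ± 0.23, the ER protein WFS1 by 4.22 ± 0.15 and the Golgi protein TMEM115 by 4.17 ± 0.15. All 92 lipid enzymes and all 18 ABC transporters rose, with 168 of 177 solute carriers. The scaffold DLG1 and the SNARE protein STX7 each fell by 1.74 (SE 0.30 and 0.39). In all, 1885 genes rose and 1318 fell, against 1444 and 2574 with scaling on the secreted and luminal lists and 760 and 7171 with library size alone. The genes that fell numbered 861 without IP 3 of the EMC10 line and 743 with DESeq2. Under library size alone 71 lipid enzymes rose and 2 fell, 144 solute carriers rose and 5 fell, and 18 ABC transporters rose.

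Across the lines, 1437 genes rose with all 3 baits and 381 fell with all 3. The EMC7 and EMC10 lists of rises shared 1733 genes, against 385 for independent lists, and the EMC6 list shared 1494 with EMC7 (340.0 for independent lists) and 1492 with EMC10 (332). Opposite directions were called for 2 genes between EMC6 and EMC7, 1 between EMC6 and EMC10 and 0 between EMC7 and EMC10. Across genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.75 to 0.82.

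Over the mean of the 3 lines, messages of multi-pass membrane proteins rose nearly as a whole: 539 of the 549 tested members of the 9 multi-pass lists rose and 2 fell. The single-pass lists followed with 246 of 304 risen and 2 fallen, then the secreted and ER luminal lists with 105 of 209 risen and 5 fallen. Of 223 cytosolic and histone messages, 1 rose and 149 fell. Under library size alone 469 multi-pass messages rose and 5 fell, 78 single-pass rose and 108 fell, 11 secreted and luminal rose and 140 fell, and 221 cytosolic and histone messages fell. With scaling on the secreted and luminal lists the single-pass counts were 182 and 33 and the secreted and luminal counts 57 and 56. List medians are given relative to the median of all tested genes. Taken per pair of IP and input, the multi-pass median exceeded the single-pass median by 1.26 ± 0.30 (SD, 7 pairs) and the luminal median by 1.69 ± 0.16, the single-pass median exceeded the luminal one by 0.43 ± 0.14, and the luminal median exceeded the cytosolic one by 0.76 ± 0.10. Each held in 7 of 7 pairs, with p = 0.015625 in a two-sided exact sign-flip permutation test, the smallest that 7 pairs can give, and 0.015625 after adjustment over the 4 contrasts. The test took the 7 pairs as independent, although they are replicates of 3 lines, so its p does not measure the spread between lines or baits. These contrasts and their test were chosen after the data were seen.

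Among the multi-pass lists, the ABC transporters stood 2.96 above the median of all genes, with TAP2 at 4.17 ± 0.22 and ABCC4, an exporter of organic anions, at 4.06 ± 0.10. The P-type pumps stood at 2.95 (27 of 27 risen), with the lipid flippase subunits ATP11A and ATP11B at 3.65 and 3.61. The ion channels stood at 2.84 (87 of 90), with CACNA1C at 4.73 ± 0.19, CACNA1D at 4.39 ± 0.15 and CACNA1B at 4.29 ± 0.18. The solute carriers stood at 2.62 (171 risen and 2 fallen of 177), with SLC12A2 at 4.15 ± 0.10 and the zinc transporter SLC30A5 at 4.08 ± 0.11. The lipid enzymes stood at 2.32 (91 of 92), with the phosphatidylserine synthase PTDSS1 at 3.90 ± 0.10 and, from its N-glycan part, the oligosaccharyltransferase subunit STT3B at 4.06 ± 0.09. Camera called each of these lists with a preset correlation, and each held with an estimated correlation (adjusted p = 0.0281 for every one of them).

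Other multi-pass lists rose in full by count but were lost with an estimated correlation. The 29 class A G protein-coupled receptors stood at 2.18, with the bradykinin receptor BDKRB2 at 3.81 ± 0.39 (adjusted p = 0.163 with an estimated correlation), and the 20 DHHC palmitoyltransferases at 1.94, with ZDHHC16 at 2.59 ± 0.12 (adjusted p = 0.112 with an estimated correlation). A list of receptors and other multi-pass proteins made with a signal peptide, below called receptors with a signal peptide, had 43 members. It stood at 1.58, with the Frizzled receptor FZD9 at 2.86 ± 0.17 (adjusted p = 0.154 with an estimated correlation). The 53 tetraspanins, claudins and related proteins stood lowest at 1.38, with SYNGR1 at 2.64 ± 0.11 (adjusted p = 0.170 with an estimated correlation). Under library size alone 26 of the class A receptors, 17 of the palmitoyltransferases and 28 of the receptors with a signal peptide rose, and 25 of the tetraspanin and claudin list rose and 2 fell. The olfactory receptor OR51E2, outside the lists, went from 2.65 ± 0.49 to 29.2 ± 5.5 CPM with EMC10 and from 2.54 ± 0.96 to 24.5 ± 8.1 CPM with EMC7, and had 0 counts in both EMC6 inputs.

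The single-pass lists, of type II Golgi enzymes and of type I proteins made with a signal peptide, and the secreted and luminal lists moved less. Type II Golgi enzymes stood at 1.21 (85 of 94 risen, 87 adjusted over the list alone, but 24 risen and 19 fallen with library size alone), with the mannosidase MAN2A2 at 1.86 ± 0.15, and type I proteins at 0.99 (161 risen and 2 fallen of 210, but 54 and 89 with library size alone), with the semaphorin receptor PLXNA3 at 1.70 ± 0.12. The adjusted p with an estimated correlation was 0.351 and 0.427. Secreted proteins stood at 0.58 (74 risen and 5 fallen of 154), with the lysosomal enzyme GAA at 1.52 ± 0.13, and ER luminal proteins at 0.53 (31 of 55), with the glucosidase subunit GANAB at 1.25 ± 0.08; their adjusted p was 0.753 and 0.573 with an estimated correlation. Under library size alone 5 secreted messages rose and 101 fell, and 6 luminal messages rose and 39 fell. With scaling on these lists themselves, which places them near 0, the counts were 41 and 37, and 16 and 19. The secreted list was not called without IP replicate 2 of the EMC6 line (camera adjusted p = 0.156) or IP replicate 1 of the EMC7 line (0.0629).

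Most lists outside the secretory pathway lay near or below the median of all genes. Ribosomal proteins stood at -0.26 (65 of 81 fallen), the proteasome, chaperonin and translation factor list at -0.19 (70 of 99 fallen and 1 risen), and histones at -0.06 (14 of 43 fallen). The 1 that rose was EIF2AK3 (1.09 ± 0.14), the ER-membrane kinase PERK, which shares a symbol stem with initiation factors. Respiratory chain subunits had a median of 0.02 and a mean log2 change of -0.14 (6 risen and 25 fallen of 84), with NDUFA9 at 1.30 ± 0.10. These lists had adjusted p = 0.441 with an estimated correlation. Tail-anchored proteins, which are inserted after translation ends, stood at -0.10 (1 risen and 13 fallen of 44; adjusted p = 0.154 with an estimated correlation), with STX7 at -1.45 ± 0.26. Without IP replicate 2 of the EMC6 line camera gave adjusted p = 0.0703 for the tail-anchored list and 0.0547 for the respiratory chain. Mitochondrial carriers, multi-pass proteins outside the ER, stood at 0.27 (5 risen and 1 fallen of 26, but 1 and 20 with library size alone; camera adjusted p = 0.838). Taken per pair, the mitochondrial carriers lay above the median of all genes in 6 of 7 pairs, and the respiratory chain, whose median of the fit was 0.02, below it in 7 of 7 pairs (mean of pairs -0.0496 ± 0.0411, SD). In the two-sided exact sign-flip permutation test, chosen after the data were seen, all 24 lists passed after adjustment, 19 above and 5 below that median (adjusted p = 0.0170, or 0.03125 for the mitochondrial carriers and histones), so it does not separate lists with a small shift from those with a large one. With library size alone 81 ribosomal protein, 98 proteasome, chaperonin and translation factor, 42 histone and 42 tail-anchored messages fell, and the respiratory chain had 1 risen and 82 fallen, or 1 and 63 with scaling on the secreted and luminal lists and 9 and 13 with DESeq2 size factors. RPL and histone genes share near-identical copies, and ISY1 and ISY1-RAB43 overlap, so their counts are uncertain.

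Messages of the ER machinery itself also rose. Of 30 translocon and oligosaccharyltransferase subunits 27 rose, with STT3A at 3.66 ± 0.09 and SEC63 at 2.11 ± 0.10 (list median 0.95, with 8 risen and 15 fallen under library size alone; adjusted p = 0.170 with an estimated correlation). Of 11 subunits of the multi-pass translocon and GET insertase 8 rose, with CCDC47 at 2.19 ± 0.08 and TMEM147 at 2.01 ± 0.11 (median 0.83, with 3 risen and 6 fallen under library size alone; adjusted p = 0.154 with an estimated correlation). Of 10 EMC subunits 7 rose, the 3 baits among them. Without the bait messages 4 of 7 rose (list median 0.90; adjusted p = 0.0277 with an estimated correlation), a test chosen after the data were seen. The full EMC list had 6 risen and 3 fallen under library size alone, and 6 and 2 with scaling on the secreted and luminal lists. Sterol-regulated genes had 13 risen and 4 fallen of 23, or 10 and 10 under library size alone (adjusted p = 0.0281 with an estimated correlation); among the risen members, DHCR7 (2.75 ± 0.09) and SREBF2 (2.31 ± 0.11) are ER membrane proteins. Stress-response targets had 9 risen and 2 fallen of 27, or 2 and 20 under library size alone (camera adjusted p = 0.729, although the list median lay above that of all genes in 7 of 7 pairs, by 0.30 ± 0.12, SD), led by the cystine transporter SLC7A11 at 2.45 ± 0.31. In all, 2243 genes rose and 2547 fell, against 1704 and 5162 with scaling on the secreted and luminal lists, 2355 and 1616 with DESeq2, and 1135 and 7282 with library size alone.

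**Figure D2:**
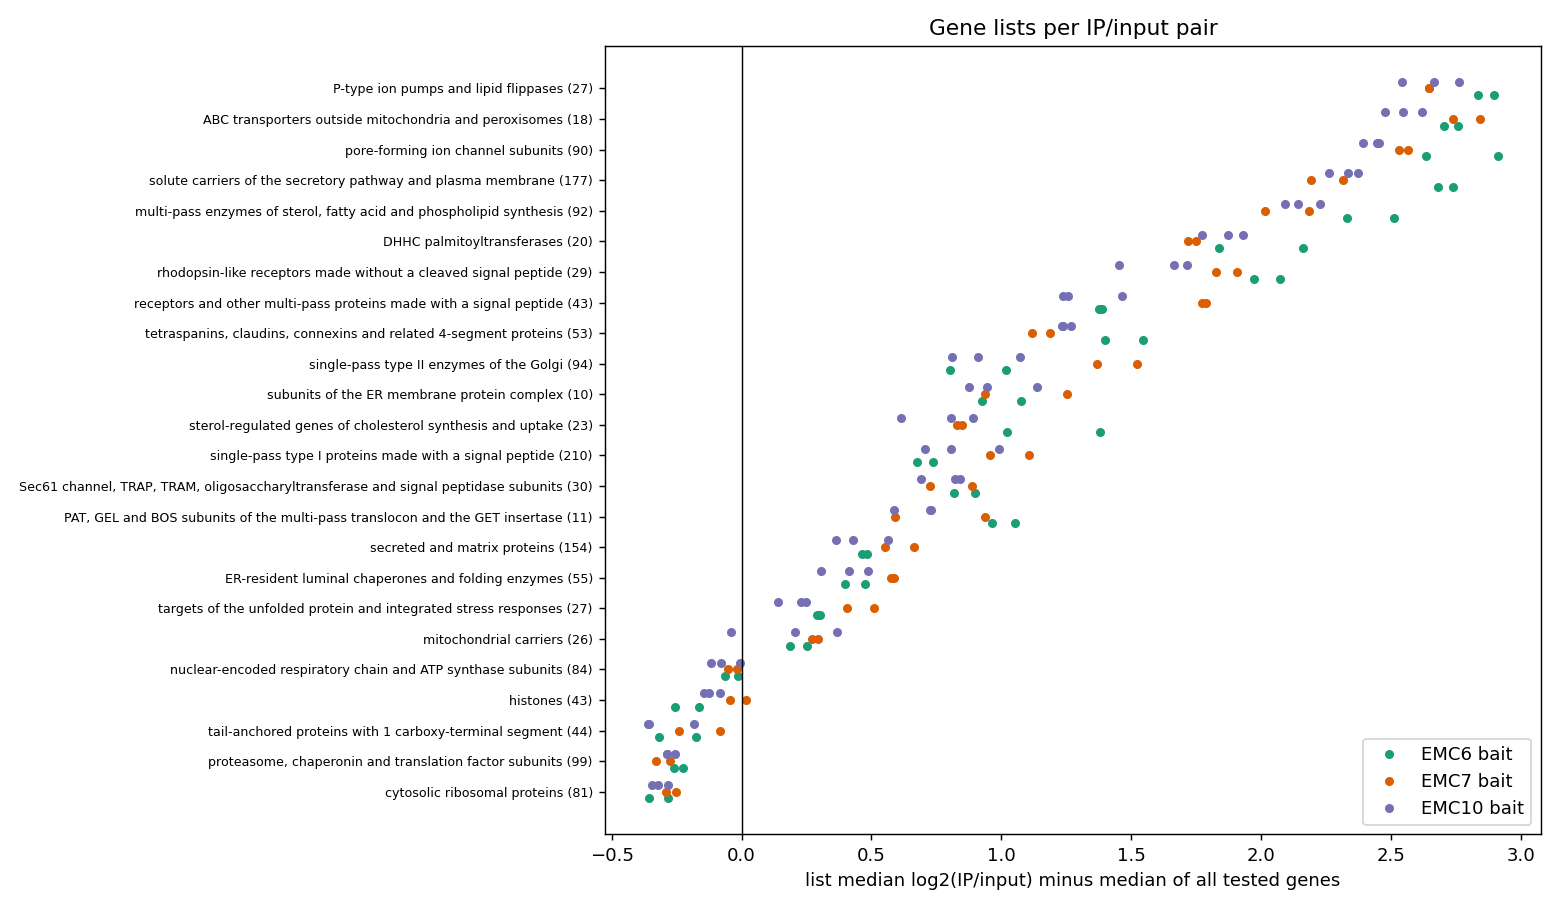
Median log2(IP/input) of each gene list minus the median of all tested genes (horizontal axis), 1 point per IP/input pair, coloured by bait, with the number of tested members in parentheses. Every pair of the P-type pump list lies at 2.54 or above, and every pair of the ribosomal protein list lies below 0.

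Differences between baits were tested as differences of the IP/input changes. EMC1 was enriched more with EMC7 than with EMC10 by 1.61 ± 0.21 (adjusted p = 1.63e-05) and more than with EMC6, with a difference for EMC6 against EMC7 of -1.48 ± 0.23 (adjusted p = 0.000447), or -2.73 when the IP libraries were compared directly. The type II Golgi enzymes lay 0.53 higher with EMC7 than with EMC10 relative to all genes (2 of 94 risen, 35 adjusted over the list alone) and 0.57 higher than with EMC6 (difference -0.57, 6 fallen, 21 adjusted over the list alone). The latter difference was -1.50 with the IP libraries compared directly and -0.23 without input 2 of the EMC6 line. With an estimated correlation the adjusted p was 0.424 against EMC10 and 0.580 against EMC6. SLC12A2 was enriched more with EMC6 than with EMC10 by 2.06 ± 0.21 (adjusted p = 2.37e-08), and ASB13 by 5.14 ± 0.65 (adjusted p = 5.27e-06). Between the IP libraries alone SLC12A2 differed by 0.89, so the larger part of its difference lay in the inputs, and ASB13 by 5.04.

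The number of genes that separated the baits depended on the fit. Without pairing, EMC6 against EMC7 gave 18 genes higher and 31 lower, EMC6 against EMC10 gave 6 and 1, and EMC7 against EMC10 gave 14 and 1, the baits included. With IP and input paired in a replicate block the counts were 597, 211 and 414, and with DESeq2 they were 132, 12 and 45. Library size alone gave 195 higher and 21 lower, 493 and 1, and 95 and 1 in the same order. For EMC6 against EMC7, scaling on the secreted and luminal lists gave 44 and 35, and the fit without LSM4 and MAP4 gave 32 and 15. Without input 1, IP 1, input 2 or IP 2 of the EMC6 line, EMC6 against EMC7 gave 16 higher and 158 lower, 91 and 11, 251 and 19, and 12 and 74, so the balance of directions turned with single EMC6 libraries. Without those of the EMC7 line it gave 16, 18, 11 and 14 genes. EMC6 against EMC10 gave 17 without IP 1 and 227 without input 2 of the EMC6 line. EMC7 against EMC10 gave 82, 32, 80 and 34 without those of the EMC6 line, 3, 7, 3 and 3 without those of the EMC7 line, and 7, 6, 6, 5 and 8 without IP 1, input 2, IP 2, input 3 and IP 3 of the EMC10 line. Solute carriers lay 0.50 and 0.37 higher with EMC6 than with EMC7 and EMC10 in these differences, but -0.42 and -0.46 when the IP libraries were compared directly, a comparison chosen after the data were seen. Their higher enrichment with EMC6 thus lay in its lower inputs, not in higher IP values. No list held with an estimated correlation, where the adjusted p was 0.580 for the solute carriers in EMC6 against EMC7.

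**Figure D3:**
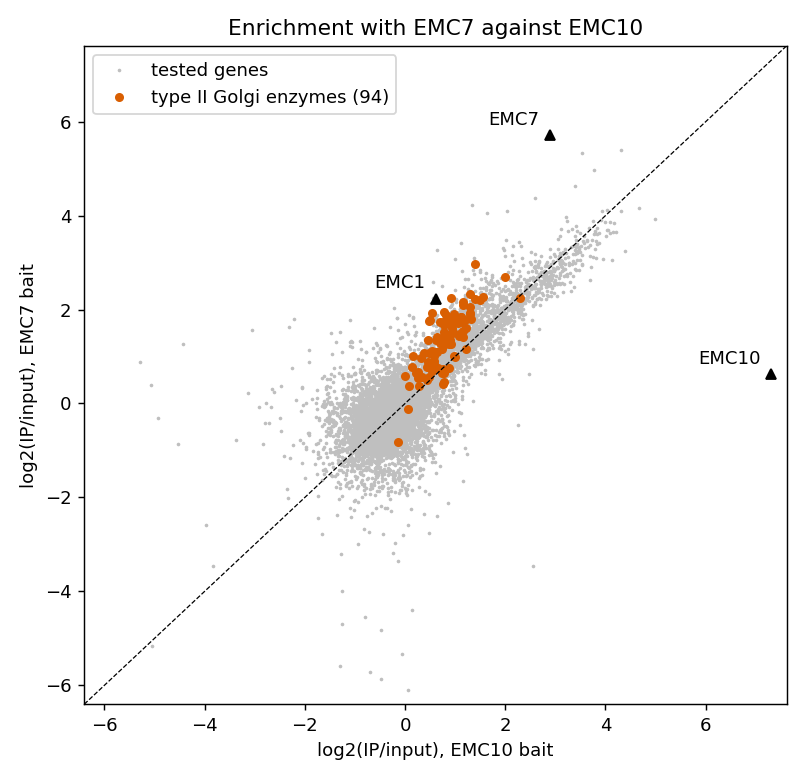
Fitted log2(IP/input) of each tested gene with the EMC10 bait (horizontal) and the EMC7 bait (vertical), the dashed line marking equal change. The 94 type II Golgi enzymes (orange) lie mostly above the line, and EMC1 lies at 2.23 with EMC7 against 0.62 with EMC10.

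The inputs of the EMC6 line were compared with those of the other lines, as the lines differ in genotype. Messages made at the ER were lower in the EMC6 line: 51 of 55 ER luminal proteins fell (median -1.08 relative to all genes), with 166 of 210 type I proteins (-0.93; 7 rose), 80 of 92 lipid enzymes (-0.99; 1 rose), 27 of 30 translocon subunits (-1.06) and 111 of 177 solute carriers (-0.93; 7 rose). These inputs also differed in other ways: 11.0% and 12.1% of their counts lay outside genes, against 4.23% to 4.71% in the other inputs. The luminal less cytosolic median was -1.35 in EMC6 input 1 but -0.45 in input 2, against -0.32 to -0.0559 in the others. Without input 1 the luminal and solute carrier lists stood at -0.92 and -0.67, and without input 2 at -1.23 and -1.22. The adjusted p with an estimated correlation was 0.207 for the luminal, type I, lipid and translocon lists and 0.226 for the solute carriers. Scaling on the secreted and luminal lists gave 3 higher and 18 lower luminal, 31 and 57 type I, 8 and 26 lipid, 2 and 10 translocon and 26 and 43 solute carrier messages. EMC1 fell by 1.21 (SE 0.14), EMC3 by 0.68 (SE 0.15) and EMC4 by 0.58 (SE 0.16), although EMC3 and EMC4 stood at 0.10 and 0.19 when libraries were scaled on the secreted and luminal lists. CDH3, a cadherin, had 0.352 ± 0.014 CPM in the EMC6 line against 47.4 ± 9.3 and 52.2 ± 8.8 CPM in the EMC7 and EMC10 lines, and the sodium leak channel NALCN had 0.342 ± 0.484 CPM, 2 counts in all, against 11.9 ± 0.9 and 10.3 ± 2.2 CPM.

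A few messages were far higher in the EMC6 line. LSM4, an RNA-binding Sm-like protein (chromosome 19, 18306236 to 18323076), had 26288 ± 5270 CPM in its inputs against 60.8 ± 6.4 and 62.1 ± 5.4 CPM in the others, and MAP4, a microtubule-associated protein (chromosome 3, 47850695 to 48088848), had 13299 ± 4161 against 86.8 ± 9.5 and 90.8 ± 4.4 CPM. Together these genes took 5.38% to 7.36% of the gene counts in EMC6 inputs and 11.3% to 13.4% in EMC6 IPs, and at most 0.0209% elsewhere. FBXO27 had 169 ± 14 CPM in the EMC6 inputs, 0 counts in the EMC7 inputs and 0.297 ± 0.335 CPM in the EMC10 inputs, and SPEG had 192 ± 6 against 0.743 ± 0.595 and 0.902 ± 0.450 CPM. The counts per gene do not show whether these footprints came from the endogenous messages, from inserted sequence in this line or from contaminating fragments. In all, 1445 genes were higher and 2066 lower. Line, bait and genotype cannot be told apart in this comparison. Scaling on the secreted and luminal lists gave 5672 higher and 511 lower, library size alone 3434 and 1452, and DESeq2 713 and 2050.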

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

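The differences between baits given here passed a test of the difference of the IP/input changes itself, with edgeR's quasi-likelihood test for genes and camera for lists. The gene counts below, 49, 7 and 15, are those of the fit without pairing, whereas the replicate block gave 597, 211 and 414 in the same order. The tests of explanations for EMC1, for the type II Golgi enzymes and for the inputs of the EMC6 line were chosen after those results were seen, as was the direct comparison of IP libraries. The splits of the libraries were planned.

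Between EMC6 and EMC7, 49 genes differed. Beside EMC6 itself (6.37), the messages higher with EMC6 were led by ASB13 (4.02), the sedoheptulose kinase SHPK (2.90), CACNA1B (2.77) and MAP4 (2.40). SHPK (chromosome 17, 3608240 to 3636250) lies near EMC6 (3668812 to 3669665), the gene knocked out in the EMC6 line. An effect of that site was not tested. SHPK also overlaps a neighbouring gene on that chromosome, so its counts are uncertain. CACNA1B had 3 and 8 counts in the EMC6 inputs against 56 and 20 in the EMC7 inputs. In the IPs it had 40 and 132 against 121 and 80. Its difference thus rests in part on few input counts. Lower with EMC6 were ARHGEF11 (-3.91), the growth factor BMP8B (-3.45), EMC7 (-2.45), the phosphatase regulator PPP1R7 (-2.27), the mannosidase MAN2A2 (-1.76) and EMC1 (-1.48). In the EMC6 IPs ARHGEF11 had 0 and 2 counts, BMP8B 3 and 1, and PPP1R7 2 and 6, so the sizes of these differences are uncertain. ASB13 passed under 25 of 25 alternatives and EMC1 under 25 of 26. MAN2A2 passed under 11 of 26, PPP1R7 under 14, SHPK and BMP8B under 16, ARHGEF11 under 19 and CACNA1B under 21 of 25. When input 2 of the EMC7 line was left out, the adjusted p was 0.200 for MAN2A2, 0.102 for PPP1R7, 0.150 for SHPK and ARHGEF11 and 0.126 for BMP8B, and without input 1 of that line it was 0.211 for CACNA1B.

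Between EMC6 and EMC10, 7 genes differed, among them EMC6 (6.44), ASB13 (5.14), MAP4 (2.30), the cotransporter SLC12A2 (2.06), LSM4 (1.77) and EMC10 (-6.83). SLC12A2 passed under 26 of 26 alternatives, although at 0.89 with the IP libraries compared directly, and ASB13 under 25 of 25. Between EMC7 and EMC10, 15 genes differed, among them EMC7 (2.81), EMC1 (1.61), the Hedgehog release protein DISP1 (1.44), the lipid droplet protein seipin, encoded by BSCL2 (1.33), and EMC10 (-6.70). EMC1 passed under 25 of 25 alternatives with a range of 1.44 to 1.71, DISP1 under 19 of 25 and BSCL2 under 10 of 25. BSCL2 was lost without any 1 of the EMC7 or EMC10 libraries, and DISP1 without input 1, input 2 or IP 2 of the EMC7 line or input 3 of the EMC10 line (adjusted p = 0.116, 0.0688, 0.121 and 0.0516).

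List medians relative to all genes were higher with EMC6 than with EMC7 for solute carriers (0.50), P-type pumps (0.42), lipid enzymes (0.42), DHHC palmitoyltransferases (0.31), tetraspanins and claudins (0.27), sterol-regulated genes (0.25) and translocon subunits (0.23). The medians of these lists turned when the IP libraries were compared directly, to -0.42, -0.58, -0.61, -0.60, -0.67, -0.24 and -0.83 in the order given, with the sterol-regulated genes no longer called. That comparison leaves out the inputs, where these lists were lower relative to all genes in the EMC6 line than in the other lines. The higher enrichment with EMC6 thus lay in its lower inputs, not in higher IP values. EMC6 was lower than EMC7 for type II Golgi enzymes (-0.57), type I proteins (-0.24), histones (-0.22), receptors with a signal peptide (-0.20), ER luminal proteins (-0.16) and secreted proteins (-0.10). Between the IP libraries these stood at -1.50, -1.03, 0.0366, -1.07, -1.21 and -0.82 in the order given, with the histones turned and not called. Against EMC10, EMC6 was higher for solute carriers (0.37), ion channels (0.29), class A receptors (0.28), lipid enzymes (0.28), P-type pumps (0.27), tetraspanins and claudins (0.27), palmitoyltransferases (0.22), ABC transporters (0.21), sterol-regulated genes (0.16) and translocon subunits (0.15), and lower for histones (-0.17). The class A receptors were not called there in the replicate block. The IP libraries compared directly turned the medians of all the lists higher against EMC10, from -0.12 for the sterol-regulated genes to -0.82 for the translocon subunits. These differences thus lay in the inputs as well. EMC7 exceeded EMC10 for type II Golgi enzymes (0.53), receptors with a signal peptide (0.46), type I proteins (0.20), ER luminal proteins (0.15) and secreted proteins (0.14), and lay lower for solute carriers (-0.16), lipid enzymes (-0.16) and the EMC subunits (-0.0693). The EMC list holds the baits: 2 members rose and 1, EMC10 itself, fell, and the list was not called in the replicate block (adjusted p = 0.910). With an estimated correlation none of these lists was called: the adjusted p was 0.580 to 0.809 for EMC6 against EMC7, 0.843 against EMC10, and 0.424 or 0.953 for EMC7 against EMC10.

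Single EMC6 libraries decided several of these list calls. Without input 1 or IP 2 of the EMC6 line, EMC6 against EMC7 was not called for the P-type pumps (adjusted p = 0.175 and 0.203), the palmitoyltransferases (0.535 and 0.314), the tetraspanins and claudins (0.277 and 0.328) or the translocon subunits (0.289 and 0.203). Without input 2 or IP 1 of that line it was not called for the type I proteins (adjusted p = 0.923 and 0.392), the luminal proteins (0.923 and 0.474) or the receptors with a signal peptide (0.923 and 0.516). The secreted list turned to 0.24 and was called the other way without input 2 (adjusted p = 0.0341), and stood at 0.13 without IP 1 (0.316); it was not called without IP 1 or input 2 of the EMC7 line (0.285 and 0.758). The histones were not called without input 1 or IP 2 of the EMC6 line (0.985 and 0.858). The solute carriers, lipid enzymes, sterol-regulated genes and type II Golgi enzymes were called without any 1 library in EMC6 against EMC7. In EMC6 against EMC10, without IP 2 of the EMC6 line no list was called but the solute carriers and lipid enzymes (adjusted p = 0.0626 to 0.947 for the others), and the ABC transporters turned to -0.12. Without input 1 of that line the sterol-regulated genes were called as well (0.435 to 0.799 for the others), and the ion channels and palmitoyltransferases turned to -0.0161 and -0.0761. In EMC7 against EMC10, without IP 2 of the EMC7 line the solute carriers, the lipid enzymes and the EMC subunits were not called (adjusted p = 0.255, 0.255 and 0.279), nor were the secreted proteins without IP 1 or input 2 of that line (0.268 and 0.577).

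EMC1 was enriched more with EMC7 than with EMC10, by 1.61. The median difference of the 210 other type I messages was 0.24 (SD 0.36), so a gain of that size would not reach the EMC1 difference. EMC1 was taken up for its large difference, so this comparison cannot exclude that EMC1 shares a general gain of type I messages with EMC7. The values argue against a difference between the inputs, since the IP libraries compared directly differed by 1.69 (adjusted p = 2.69e-10). The higher footprint density on the bait stays open: EMC7 stood 4.05 higher on the log2 scale in the EMC7 inputs than in the EMC10 inputs, and bait, line and bait level cannot be told apart. No biological explanation was tested.

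Type II Golgi enzymes were enriched more with EMC7 than with EMC10, by 0.53 in the list median, a call lost with an estimated correlation (adjusted p = 0.424). In the inputs the list median was 0.0754 higher with EMC7, a difference in the wrong direction to raise an IP/input ratio. A gain shared alike with luminal messages was argued against by the type II median less the luminal median, which was 0.80 and 0.89 in the EMC7 pairs against 0.55, 0.46 and 0.49 in the EMC10 pairs, a difference of 0.34 (SD of pairs 0.055), although receptors with a signal peptide (0.46), type I proteins (0.20) and secreted proteins (0.14) were called higher too at the preset correlation (adjusted p = 0.953 for each with an estimated one), so a wider gain of such messages stays open. An exact two-sided permutation of the 5 pairs gave p = 0.1 for the list median itself, the smallest that 10 splits allow, so the spread between pairs stays open, as do line and bait level, and no biological explanation was tested.

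Messages made at the ER were low in the inputs of the EMC6 line, which is also the knockout line. LSM4 and MAP4 taking counts would lower the other genes of a library alike, which is argued against by the luminal less cytosolic median, lower by 0.74 (-0.74; SD of libraries 0.38), at -1.35 and -0.45 in the EMC6 inputs against -0.32 to -0.0559 in the others. Input 2 alone lay close to the others on this measure, but without both messages the luminal list still stood at -1.08 in the fit. A loss limited to multi-pass messages was argued against by the luminal median, which was lower by 0.70 (-0.70), at 1.79 and 2.21 in the EMC6 inputs against 2.61 to 2.77 in the others. A larger share of cytosolic ribosomes stays open: 13 of 13 membrane and luminal lists lay below every cytosolic list, although the multi-pass less luminal median also differed by -0.15, more than the spread of libraries. The loss of endogenous EMC6, the cell clone and the preparation of microsomes and libraries, whose share of reads outside genes also differed, cannot be told apart here.

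For IP against input over the mean of the 3 lines, 1 of 100 drawn splits of the 14 libraries, the real one, called as many genes with line as a covariate. It called 4794 and the highest of the others 1674. The real split is 1 of the 100, so this share, under 0.05, is the smallest the test can give. The drawn splits did not keep the pairs and took the samples as separate units, though replicates may be technical. Among the 64 splits that part every pair of IP and input, the highest of the others called 1921 and differed from the real one by 1 turned pair. For the EMC10 line alone, 1 of 10 splits called as many genes (3411, highest other 0), and 10 splits are too few for a share under 0.05.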

How the results depend on the processing

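The direct comparison of IP libraries, the fit without LSM4 and MAP4, the mean without the EMC6 line, the lists without the bait messages and the exact sign flips over pairs for lists were chosen after the data were seen. Over the alternatives to the fit, results for named genes kept a call or its absence 6301 times, lost the call 217 times, gained it 28 times and turned 12 times. For lists with camera at the preset correlation these counts were 3424, 99, 121 and 28. A turn was counted only for results called in the main fit. Changes of sign in uncalled results are among those kept or gained. Other set tests are not in these counts: of 130 list calls over all comparisons, the estimated correlation lost 103, among them all those between baits (13, 11 and 8) and all 16 in the inputs, and fry's directional test lost 37, again all those between baits, 1 and 3 with EMC6 and EMC7, 1 in the inputs and 0 over the mean. Over the mean of the 3 lines, 21 of 21 alternatives called the solute carriers (2.48 to 2.70), ABC transporters (2.80 to 3.06), P-type pumps (2.74 to 3.09), ion channels (2.72 to 3.07), lipid enzymes (2.23 to 2.43) and type II enzymes (1.04 to 1.34), leaving aside the estimated correlation, under which the type II enzymes were lost (adjusted p = 0.351) and 7 lists were called against 22, with or without the bait messages. Exact sign flips over the pairs called 24 lists, 19 higher and 5 lower. Depth limits genes with few counts; in the EMC6 line, the shallowest, 24.5% of simulated 2-fold changes were recovered, and depth and spread between replicates were not told apart. Where a fit left 1 sample in a group, that sample was assumed to vary like the others. The alternatives for predicted membrane segments were not run. The cause was not tested for the changes below, except where the construction shows it: library size moves the median of all genes, a test against a fold asks for larger changes, and the filters and the fit to the compared lines alone change the genes or libraries tested. Likewise, the direct comparison of IP libraries leaves out the inputs, so it departs from the difference of enrichments by the difference between the inputs.

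Library size alone called 5310 genes with EMC6, 7039 with EMC7, 7931 with EMC10, 8417 over the mean, 216 in EMC6 against EMC7, 494 in EMC6 against EMC10 and 96 in EMC7 against EMC10 (195, 493 and 95 of these higher). It turned EMC1 (-0.50), EMC6 (-0.0308) and MMGT1 (-0.63) with EMC10, EMC10 (-0.40) and MMGT1 (-0.43) with EMC7, and MMGT1 (-0.24), HYOU1 (-0.10), SLC25A14 (-0.14), SLC25A39 (-0.31) and TMCO1 (-0.0616) over the mean. For the luminal list, camera's direction turned while the median relative to all genes stayed at 0.52 with EMC6 and 0.53 over the mean. Scaling on the secreted and luminal lists called 79 genes in EMC6 against EMC7, 5 in EMC7 against EMC10 and 6183 in the inputs, where EMC3 and EMC4 turned to 0.10 and 0.19. DESeq2 size factors in edgeR called 22 in EMC6 against EMC7 and 6 in EMC7 against EMC10, and DESeq2 called 132, 12 and 45 in EMC6 against EMC7, EMC6 against EMC10 and EMC7 against EMC10. Without LSM4 and MAP4, EMC6 against EMC7 gave 47 genes, 32 higher and 15 lower. Without the EMC6 line the mean gave 4154.

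A test against a fold of 1.5 called 1231, 1581 and 1384 genes with EMC6, EMC7 and EMC10, 1823 over the mean, 1187 in the inputs, 5 in EMC6 against EMC7 and 3 in EMC7 against EMC10. Without a filter EMC6 against EMC7, EMC6 against EMC10 and EMC7 against EMC10 gave 103, 11 and 35 genes. A floor of 10 CPM gave 9 in EMC7 against EMC10, and the fit without the baits 8. With only the lines compared, the EMC6 line gave 1242, EMC6 against EMC7 gave 6 and EMC7 against EMC10 gave 132.

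With IP and input paired in a replicate block, the differences gave 597 genes (EMC6 against EMC7), 211 (EMC6 against EMC10) and 414 (EMC7 against EMC10). The block gained calls for EMC10 with the EMC6 bait (0.52, adjusted p = 0.00103) and EMC3 in EMC6 against EMC10 (-0.35, 0.0484). Among lists it gained secreted with EMC6 (0.49, 0.00178) and EMC10 (0.49, 0.00900), luminal with EMC10 (0.45, 0.00159), ion channels in EMC6 against EMC7 (0.10, 0.0409), type I in EMC6 against EMC10 (-0.07, 0.0432) and ABC transporters in EMC7 against EMC10 (0.17, 0.00464). It lost class A receptors in EMC6 against EMC10 (0.22, 0.0776), and turned camera's direction for EMC subunits in EMC7 against EMC10 (-0.0706, 0.910). It changed no other call of a named gene or list.

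The IP libraries compared directly differed in 1878, 1814 and 307 genes in EMC6 against EMC7, EMC6 against EMC10 and EMC7 against EMC10. Against EMC7 and EMC10, camera's direction for EMC6 turned for solute carriers (-0.42 and -0.46), P-type pumps (-0.58 and -0.70), tetraspanins and claudins (-0.67 and -0.63), palmitoyltransferases (-0.60 and -0.49), lipid enzymes (-0.61 and -0.60), translocon subunits (-0.83 and -0.82) and histones (0.0366 and -0.0154), and against EMC10 for ABC transporters (-0.46), ion channels (-0.18) and sterol-regulated genes (-0.12). The medians of the sterol-regulated genes against EMC7 (-0.24) and the class A receptors against EMC10 (-0.24) turned as well, without a call and with camera's direction kept.

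Without 1 library at a time, counts ranged from 1165 to 2985 with EMC6 (lowest without IP 2 of that line), from 7 to 227 in EMC6 against EMC10, from 11 to 270 in EMC6 against EMC7 and from 3 to 82 in EMC7 against EMC10. List medians in EMC6 against EMC10 ranged from -0.12 to 0.57 for ABC transporters, from -0.0161 to 0.67 for ion channels, from -0.0761 to 0.58 for palmitoyltransferases and from -0.42 to -0.000638 for histones. In EMC6 against EMC7 they ranged from -0.48 to -0.00464 for histones and from -0.47 to 0.24 for secreted proteins. Each end of these list ranges came without a library of the EMC6 line.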

Other observations

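The groups by symbol stem were chosen after the data were seen. Among 256 stems with at least 5 tested members, some groups of membrane protein and enzyme genes rose together over the mean of the 3 lines. A stem is a name and can mix proteins of different topology. All 6 adenylyl cyclases (ADCY) rose, with a median 3.17 above all genes, as did all 15 MFSD transporters (2.73), all 5 SLCO organic anion transporters (2.56), all 6 PAQR receptors (2.12) and all 5 TLCD lipid proteins (1.85). Of 5 DPY genes, which include C-mannosyltransferases, 4 rose (3.11), and of 6 ALG enzymes of N-glycan precursor synthesis 5 rose (1.55). Of 133 TMEM genes 112 rose and 2 fell (1.43), and of 6 DHRS dehydrogenases 4 rose (1.36). Zinc finger, DEAD-box helicase and RNA-binding motif genes lay lower: 56 of 172 ZNF (-0.32), 20 of 31 DDX (-0.33) and 20 of 31 RBM genes (-0.34) fell. No median of these stems changed sign under the other scalings, but the counts depended on them. Library size alone left 66 TMEM genes risen and 23 fallen, 3 and 2 ALG, 4 and 1 DPY, 3 and 1 DHRS and 4 and 0 TLCD genes, and 162 ZNF, 31 DDX and 31 RBM genes fell. Scaling on the secreted and luminal lists gave 91 and 6 TMEM, 5 and 1 ALG, 4 and 1 DPY and 4 and 1 DHRS genes, and 117 ZNF, 27 DDX and 28 RBM genes fell. With DESeq2 size factors 42 ZNF genes fell and 1 rose, and 18 DDX and 17 RBM genes fell. Camera called these stems at the preset correlation, but none with an estimated one, where the adjusted p was 0.169 for MFSD and DPY and 0.596 for the others.

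All 12 tested cytochrome P450 messages (CYP) outside the fixed lists rose, with a median 2.24 above all genes; 11 rose with library size alone or with scaling on the secreted and luminal lists. These enzymes are held in the ER membrane by an N-terminal anchor, with the catalytic domain in the cytosol. Their median lay above those of the class A receptors, the palmitoyltransferases, the receptors with a signal peptide and the tetraspanins and claudins. The lower values of the single-pass lists thus do not stand for every message of an anchored protein. CYP7B1, an oxysterol hydroxylase, rose by 2.61 ± 0.28 on the log2 scale, CYP2S1 by 2.43 ± 0.14 and CYP4X1 by 2.23 ± 0.12, and the lowest was the retinoic acid hydroxylase CYP26B1 at 1.01 ± 0.40. The stem was picked from 256 after its values were seen, and its adjusted p was 0.596 with an estimated correlation.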
